A study of Mus musculus with 10 samples.

How the data were processed

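Gene expression was measured in mouse Lewis lung carcinoma cells, a lung tumour line from C57BL/6 mice. The cells stably carried either TDAG8 (gene symbol Gpr65), a proton-sensing G protein-coupled receptor, or the empty vector, and are called here the TDAG8 line and the control line. Per the labels, both lines were starved of serum for 12 h and then kept in medium at pH 6.4 or pH 7.4 for 4 or 12 h, and each line was also sampled before treatment. There were 10 Affymetrix Mouse430 2.0 genome arrays, 1 for each line and condition. Each array received RNA pooled from 4 separate cultures, of which 2 µg was copied into biotin-labelled cRNA.

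The deposited values are linear signal per probe set, per the deposited table, and the authors' software and summary method are not given in the sources used here. The 2% trimmed mean was 100 on every array, so the authors had scaled the arrays to a common target. The deposited signal had array medians between 11.7 and 13.8, and between 2 and 11 values per array were 0. Each array held 45101 probe sets, of which 34945 had 1 gene symbol, 932 had several, 9160 had none and 64 were control probe sets. Probe sets with several symbols or none, and the control probe sets, were left out of the gene tests, and 18193 genes remained. For 204 probe sets the gene identifier was absent from the reference gene table, and no array symbol needed updating. Genes of the lists that had no probe set with a single symbol are not analysed here.

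The array medians spanned 0.2 on the log2 scale, above the limit of 0.1, so the arrays were quantile normalised. Values were then log2(signal + 2.4), where 2.4 is the 20th percentile of all values. Each gene was represented by its probe set with the highest mean. Genes with a mean at or above the 40th percentile of all probe sets, a log2 value of 3.17, were tested, which left 12161 genes. The number of arrays limits the precision of every value.

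There were no replicates, so matched differences between conditions stood in for them. limma 3.58.1 in R 4.3.3 was used (lmFit and eBayes, moderated test, Benjamini-Hochberg adjustment over all genes, adjusted p under 0.05). The TDAG8 line was compared with the control line over 5 matched pairs of arrays with the condition as a block (4 residual degrees of freedom). pH 6.4 was compared with pH 7.4 over 4 pairs with line and time as a block (3 residual degrees of freedom). The interaction of pH and line, and the pH response within each line, came from a fit with 2 residual degrees of freedom. The 12 h arrays were compared with the 4 h arrays over 4 pairs. For differences between single arrays, genes at or beyond 1 on the log2 scale were counted without a test. The p-values measure only the spread between these arrays, since conditions stand in for replicates and pooling removed the spread between cultures.

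A set of 28 gene lists was fixed, and 26 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of each comparison. The receptor list, with 0 measured genes, and the MondoA target list, with 2, were too short. For single array differences, the percentile of a list's median among 10000 random lists of equal size and similar level was given. The comparisons, gene lists, tests, naming rule and most alternatives were fixed before the data were examined. In each tested comparison, the 8 genes with the largest rise and the 8 with the largest fall among those passing were named. Where fewer passed, genes of the same sign in every pair were ranked by their smallest absolute difference and are said not to pass, and for the interaction a pH difference of at least 0.58 in the TDAG8 line was required. Predicted genes were skipped. Up to 4 members with the largest difference were named from each list that passed or had at least 2 passing members.

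The alternatives were arrays centred on the median in place of quantile normalisation, no filter, a filter at the 60th percentile, the mean of all probe sets of a gene, eBayes with trend and robust, pseudocounts at the 5th and 40th percentiles (0.5 and 7.7), each matched pair left out in turn, no block, the treated arrays alone, and pH by time added to the model. For lists they were camera with an estimated correlation and fry, and for single array differences a limit of 0.58. Camera with an estimated correlation also takes its degrees of freedom from the residual ones of the fit. A call lost there is thus not by itself a sign of correlation among the genes. Added after seeing the data were the values as deposited, a pseudocount of 32, a filter for a signal of 50 or more on at least 1 array, and combinations of these with each other, with the pH by time term and with trend and robust. These additions were chosen after an exploratory run had shown their counts.

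The pipeline was tested on simulated data of 12161 genes per comparison, with 100 genes changed by 1 and 100 by 3 on the log2 scale, and with variances either taken from the moderated fit or drawn from its prior. For the line comparison, 93 and 100 of the 100 genes were recovered with moderated variances, and 84 and 98 with drawn variances. For pH in both lines the recovered numbers were 80 and 99, and 36 and 93. For the interaction they were 2 and 96 with moderated variances, and 0 and 0 with drawn ones. With the pH by time term, 33 and 100 were recovered with moderated variances, where 35 of 168 calls were false (20.8%), and 52 of 228 calls were false with trend and robust (22.8%). With drawn variances that model recovered 0 and 0. For the TDAG8 line alone 10 and 100 were recovered, and 0 and 78 with drawn variances. For the control line alone the numbers were 15 and 100, and 0 and 77. For time they were 74 and 100, and 53 and 98. Of the calls with moderated variances, 9.39% were false for the line comparison and 8.67% for pH in both lines. In 100 simulated sets for the interaction, camera called 16 of the unchanged lists over all 26 lists and sets, and a list shifted by 0.5 was called in 99 of the sets. The simulated noise was independent between genes, so these counts do not cover lists with correlated members. In the real data the estimated correlation of the cholesterol synthesis genes was 0.874 for pH in both lines. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, trimmed means were taken with scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.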

Results

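The 10 arrays covered 5 conditions in each of the 2 lines, namely before treatment and pH 7.4 and pH 6.4 for 4 h and 12 h, with 1 array per line and condition and no replicates. The stated aim was to find genes that the receptor TDAG8 regulates in cultured cells. The receptor gene itself was read first. The Gpr65 probe set gave signals between 0.3 and 5.3 on all 10 arrays, in the range of probe sets without expression, in the TDAG8 line as in the control line. It thus detected the transgene in neither line and gives no check of the labels, and whether its sequence lies within the expressed construct is unknown. Of the other proton-sensing receptors, Gpr4 read between 0.8 and 3.2, and the 2 probe sets of Gpr132 between 0.9 and 11.7 and between 0.6 and 6.8.

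The comparison of the lines asked which genes differed between TDAG8 and control cells whatever the pH. The matrix metalloproteinase gene Mmp3 was 7.99-fold higher in the TDAG8 line, with signals of 113 to 273 against 13 to 28 (log2 3.0, SE 0.12, adjusted p = 0.000732, higher in 5 of 5 pairs). The neighbouring membrane protein genes Tmem176b (log2 2.18, SE 0.08, adjusted p = 0.000732) and Tmem176a (2.16) were higher to a like degree, and Tmem176b read 733 to 1014 against 143 to 205. Myoz2, which encodes a protein of the muscle Z-disc, was higher by 3.15 (SE 0.31, adjusted p = 0.0217). The chemokine genes Cxcl12 (-1.58, SE 0.14, adjusted p = 0.0186) and Cxcl10 (-1.15, SE 0.11, adjusted p = 0.0217) were lower in the TDAG8 line, each in 5 of 5 pairs. Also higher were Gpr153 (2.20), an orphan receptor gene, Prxl2a (2.07), Prr9 (1.46) and C1s1 (1.3), a complement protease gene. Also lower were Ahnak2 (-1.06), the connexin gene Gjc1 (-1.05), Actl10 (-1.03), Lrrc15 (-0.98), Zc4h2 (-0.96) and the growth factor gene Fgf3 (-0.91). Prxl2a, Prr9, Actl10 and Fgf3 had signals of at most 24.5, near the lower end of the array. In the line with the lower value these 4 genes, Cxcl10, Myoz2 (1.7 to 14.0) and Gpr153 (0.3 to 10.7) read under 6.6, the level of the filter, on at least 1 array, so their log2 values depend on the pseudocount.

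**Figure D1:**
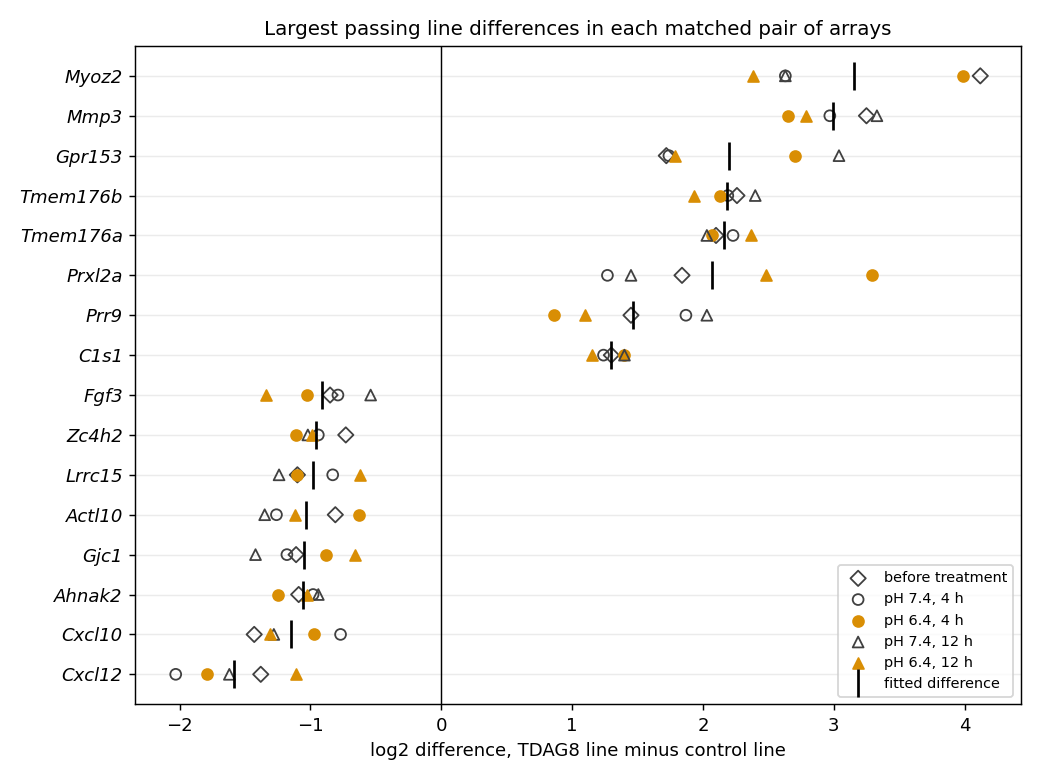
Log2 difference between the TDAG8 line and the control line for the 16 named genes with the largest passing differences, with 1 symbol per matched pair of arrays (diamonds before treatment, circles 4 h, triangles 12 h, filled at pH 6.4) and a bar at the fitted difference. Mmp3 lies between 2.65 and 3.33 in all 5 pairs, and Cxcl12 between -2.03 and -1.11.

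In total 146 of 12161 genes passed between the lines, 82 higher and 64 lower in the TDAG8 line, and 2525 had an unadjusted p under 0.05 where 608 are expected by chance. A list of glycolysis and hypoxia genes was higher in the TDAG8 line by camera (adjusted p = 3.32e-05, and adjusted p = 0.165 with an estimated correlation). Of its 18 members 0 passed over all genes and 5 adjusted over the list alone. Its largest members were the pyruvate dehydrogenase kinase gene Pdk1 (0.45), Adm (0.42), Hk2 (0.40) and Bnip3 (0.39), none of which passed. Cholesterol synthesis genes were also higher as a list (adjusted p = 0.000142, and adjusted p = 0.517 with an estimated correlation). Over all genes 0 of 16 passed and 3 adjusted over the list alone. The largest were Cyp51 (0.34), Insig1 (0.30), Sc5d (0.29) and Mvd (0.21). The cell cycle list was lower (adjusted p = 0.00146, and adjusted p = 0.517 with an estimated correlation). By gene, 0 of 25 passed either way, and Cdc6, Mcm5, Mki67 and Bub1b differed by -0.26, -0.26, -0.25 and -0.22. The list of the amino acid response and the unfolded protein response was lower too (adjusted p = 0.00283, and adjusted p = 0.517 with an estimated correlation). Taken singly, 0 of 20 passed either way, with values of -0.83 for Ddit3, -0.76 for Trib3, -0.74 for Chac1 and -0.65 for Herpud1. These came mainly from pH 6.4, and without the pH 6.4 pair at 12 h they were -0.57, -0.39, -0.44 and -0.39. The cAMP and CREB targets were higher (adjusted p = 0.0146, and adjusted p = 0.517 with an estimated correlation). Among them, 1 of 23 passed, Pde3b (0.67), and 1 adjusted over the list alone. The largest members, Nr4a3 (1.68), Nr4a2 (1.35), Pde4b (1.24) and Id3 (0.91), did not pass, and their line differences at pH 6.4 exceeded those before treatment. Epithelial markers were higher as a list (adjusted p = 0.0195, and adjusted p = 0.517 with an estimated correlation). Of the 10 markers fixed, all on the array, only 4 reached the level of the filter and were tested. Singly, 0 of 4 passed and 3 adjusted over the list alone, with values of 1.40 for Krt18, 0.51 for Krt8, 0.32 for Ocln and 0.13 for Epcam, and the first 2 differed more in the pH 6.4 pairs than in the others. Passing members of other lists were Mmp3, Cxcl10, Angpt1 (0.86), Adcy7 (0.61), Myl9 (0.86) and Dcn (0.45). Without the pair before treatment 6 genes passed, without the pH 6.4 pairs at 4 h and 12 h 11 and 28, and without the pH 7.4 pairs 4 and 8. By other settings 9 passed with no filter, 15 with no block, 6 with the treated arrays alone, 588 with a filter at the 60th percentile, 881 with trend and robust and 96 to 264 with other pseudocounts. The share of passing genes that were higher was 56.2%, and it was 65.2% with arrays centred on the median, 67.9% with the values as deposited and 51.5% with trend and robust.

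The comparison of pH 6.4 with pH 7.4 over both lines asked which acid responses the lines shared. Ccn1, which encodes a secreted matrix-associated protein, rose 13.5-fold at pH 6.4 (log2 3.76, SE 0.37, adjusted p = 0.0144, higher in 4 of 4 pairs). Its signal was 290 to 1216 at pH 6.4 and 36.4 to 41.8 at pH 7.4. The chemokine genes Cxcl2 (3.36, SE 0.35, adjusted p = 0.0149), Ccl7 (3.24, SE 0.27, adjusted p = 0.0144) and Cxcl1 (2.68, SE 0.19, adjusted p = 0.0105) rose in 4 of 4 pairs. The transcription factor gene Fos did so too (3.58, SE 0.69, adjusted p = 0.0387). Both measured MondoA targets rose, the arrestin-domain gene Arrdc4 by 3.42 (SE 0.16, adjusted p = 0.0102) and the thioredoxin-interacting protein gene Txnip by 2.56 (SE 0.16). Bnc1, a zinc finger transcription factor gene, fell by 3.66 (SE 0.25, adjusted p = 0.0105), from signals of 751 to 829 at pH 7.4 to 33.1 to 109 at pH 6.4. Srp54b (2.88) and the EGF-family gene Hbegf (2.81) also rose. Runx1t1 (-3.42), Klf3 (-2.68), Cass4 (-2.64), Dido1 (-2.47), Sertad4 (-2.46), Ppp1r10 (-2.42) and Jmjd4 (-2.42) also fell. At pH 6.4 Jmjd4 read 1.0 to 2.2, and Cass4 and Ppp1r10 read under 6.6 on at least 1 array, so these values depend on the pseudocount.

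**Figure D2:**
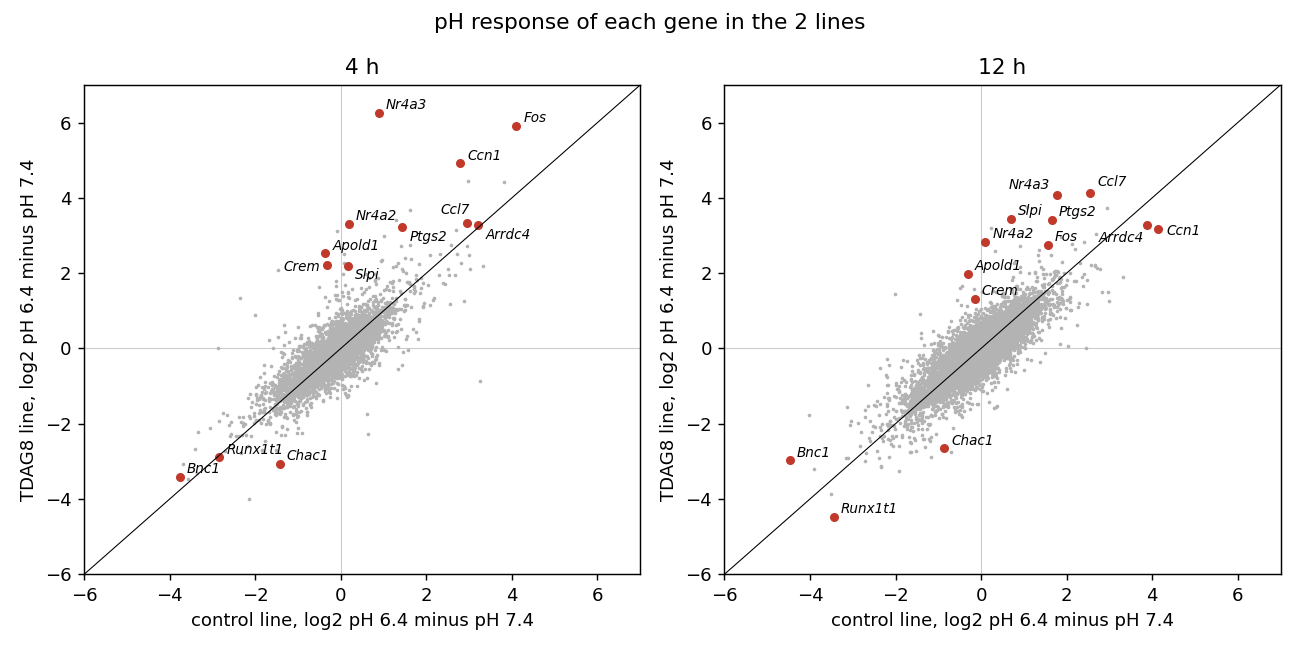
Log2 difference between pH 6.4 and pH 7.4 in the TDAG8 line (vertical) against the control line (horizontal) at 4 h (left) and 12 h (right), with 1 grey point for each of 8957 genes with a signal of 50 or more on at least 1 array, labelled genes in red, and the line of equal response. At 4 h and 12 h Arrdc4 lies at 3.29 and 3.27 in the TDAG8 line and at 3.21 and 3.89 in the control line, Bnc1 at -3.41 and -2.97 against -3.77 and -4.47, and Nr4a2 at 3.31 and 2.84 against 0.18 and 0.10.

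Of the list of inflammatory cytokines and NF-kB targets, 11 of 17 measured members rose and 0 fell, and 13 rose adjusted over the list alone (camera adjusted p = 3.5e-08, and adjusted p = 0.242 with an estimated correlation). They included Ccl2 (2.37), Cxcl10 (2.45), the cyclooxygenase gene Ptgs2 (2.44), Tnfaip3 (2.24), Ccl5 (1.83), Csf1 (1.45), Nfkbiz (1.39) and Nfkbia (0.77), and Cxcl10 and Ccl5 read under 6.6 on 1 array at pH 7.4. Of the immediate early genes 9 of 15 rose and 10 adjusted over the list alone (adjusted p = 7.69e-06, and adjusted p = 0.242 with an estimated correlation), among them Junb (2.08), Maff (2.00), Zfp36 (1.55), Klf2 (1.42) and Myc (1.14). Of the cytoskeleton list, targets of SRF, 3 of 14 rose and 5 adjusted over the list alone (adjusted p = 0.000318, and adjusted p = 0.242 with an estimated correlation), namely Myl9 (1.56), smooth muscle actin Acta2 (1.12) and Rhob (1.0). Of the cholesterol synthesis genes 2 of 16 fell and 4 adjusted over the list alone (adjusted p = 0.000318, and adjusted p = 0.751 with an estimated correlation), namely Msmo1 (-1.09) and Fdft1 (-0.84). Of the amino acid response and unfolded protein response 5 of 20 fell and 1 rose, with 6 and 1 adjusted over the list alone (adjusted p = 0.0404, and adjusted p = 0.751 with an estimated correlation). Chac1 (-2.0), which encodes a glutathione-degrading enzyme, Trib3 (-1.74), Atf4 (-1.20), Sesn2 (-1.13) and Dnajb9 (-0.67) fell, and the cystine transporter gene Slc7a11 rose by 0.60, a sign that reversed to -0.40 with the mean of its probe sets. Of the fibroblast markers 1 of 6 fell, Pdgfra (-1.70), and 1 adjusted over the list alone (adjusted p = 0.0449, and adjusted p = 0.448 with an estimated correlation).

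Other lists had passing members without passing as a list. Of 23 cAMP and CREB targets 4 rose, with 6 rising and 4 falling adjusted over the list alone (adjusted p = 0.197), including Per1 (1.57) and Nr4a1 (0.87) beside Fos and Ptgs2. Of 18 glycolysis and hypoxia genes 4 fell and 5 adjusted over the list alone (adjusted p = 0.126), namely Egln3 (-1.32), Bnip3 (-1.12), Ankrd37 (-0.88) and Hk2 (-0.77). Of the p53 targets 3 of 13 rose, with 4 rising and 1 falling adjusted over the list alone (adjusted p = 0.120), and these were Fas (1.84, a value that depends on the pseudocount, with signals of 1.0 to 6.5 at pH 7.4), Pmaip1 (1.44) and Cdkn1a (1.34). Of the TGF-beta targets 3 of 10 rose, Skil (1.32), Smad7 (0.92) and Smad6 (0.55), with 5 rising and 2 falling adjusted over the list alone (adjusted p = 0.0997). In the heat shock list Hspa1a (1.16) and Hspb1 (0.95) rose and Dnajb1 (-0.60) fell among 11 members. Of 15 angiogenic and growth factor genes Hbegf and Ereg (1.21) rose and Angptl4 (-0.69, with a signal under 6.6 on 1 array) and Angpt2 (-0.66) fell. In the oxidative stress list 2 of 10 rose, Osgin1 (0.94) and Slc7a11. Cdc6 rose (1.05) and Plk1 fell (-0.59) among 25 cell cycle genes, Gabarapl1 rose (0.79) and Bnip3 fell among 18 lysosome and autophagy genes, and Adcy6 rose (0.77) and Pde7a fell (-0.83) among 15 genes of the protein kinase A pathway. The interferon list had 1 riser, Irf7 (1.04), among 13, and the apoptosis list 1 faller, Bmf (-1.54), among 16. Among 8 other proton sensors and pH regulators, 14 matrix and protease genes, 19 oxidative phosphorylation genes, 3 histones, 6 leukocyte, 4 endothelial and 4 epithelial markers and 8 abundant reference genes, 0 passed, and the median log2 differences were 0.04, 0.01, 0.13, 0.47, 0.17, 0.08, -0.10 and 0.06.

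**Figure D3:**
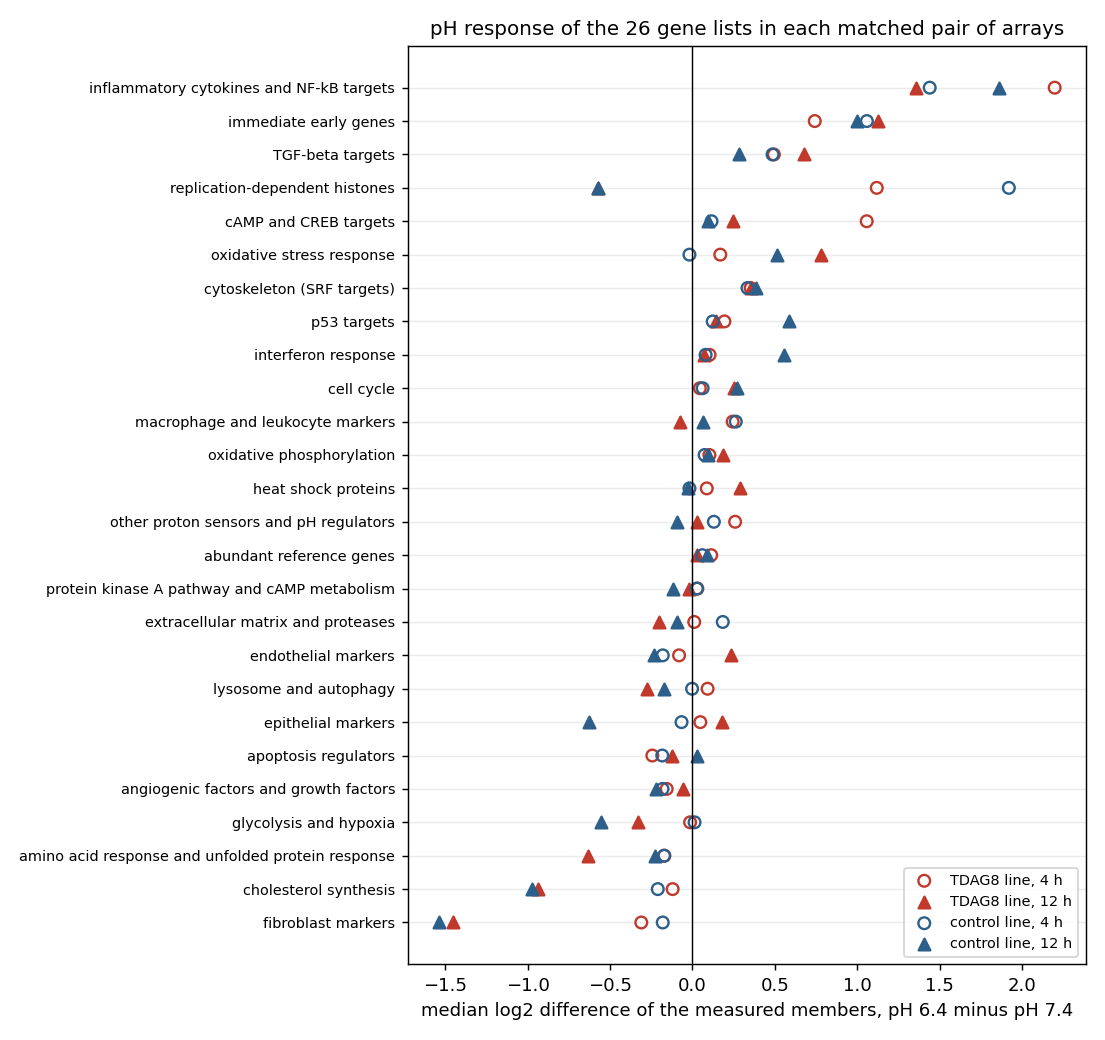
Median log2 difference between pH 6.4 and pH 7.4 over the measured members of each of the 26 tested gene lists, with 1 symbol per matched pair of arrays (red TDAG8 line, blue control line, open circles 4 h, filled triangles 12 h). The inflammatory list lies between 1.35 and 2.20 in the 4 pairs, and cholesterol synthesis moves from -0.12 and -0.21 at 4 h to -0.94 and -0.97 at 12 h.

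In total 1220 of 12161 genes passed between pH 6.4 and pH 7.4, 544 higher and 676 lower at pH 6.4, and 3883 had an unadjusted p under 0.05 where 608 are expected by chance. The probe set for the B1 repeat, a mouse interspersed element, read 2602 and 3587 on the pH 6.4 arrays at 12 h and 844 to 1456 on the other 8 arrays. Across all 12161 genes, which are not independent replicates, the pH responses of the lines correlated at 0.593 at 4 h and 0.671 at 12 h, and responses at different times at 0.361 to 0.427. Across the 8957 genes with a signal of 50 or more, a filter chosen after seeing the data, the values were 0.803, 0.834 and 0.455 to 0.545. Without the 12 h pair of either line 0 genes passed by limma, and without the 4 h pairs of the TDAG8 and control lines 44 and 278 passed. By other settings 241 passed with no filter, 1919 with a filter at the 60th percentile, 2076 with trend and robust, 1863 with no block and 3397 with pH by time in the model. The share of passing genes that rose was 44.6%, and it was 32.4% with arrays centred on the median, 33.1% with the values as deposited and 52.0% with the mean of all probe sets. Of the 1220 genes, 43 had the opposite sign with the mean of all probe sets.

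The interaction of pH and line asked where the pH response of the TDAG8 line differed from that of the control line, the question closest to the stated aim. The nuclear receptor gene Nr4a2 read 864 and 361 at pH 6.4 (4 h and 12 h) in the TDAG8 line, where its pH 7.4 signals were 84.7 and 50.1. In the control line it read 69.1 and 44.5 at pH 6.4, and 66.0 and 47.5 at pH 7.4. The pH response of Nr4a2 was larger in the TDAG8 line by 3.13 at 4 h and 2.74 at 12 h (log2 2.94, SE 0.30, adjusted p = 0.9999). Its relative Nr4a3 read 216 and 102 at pH 6.4 in the TDAG8 line and 3.0 and 10.8 in the control line (3.84, SE 0.80). At pH 7.4 it read 0.6 and 3.6, and 0.4 and 1.8, in the range of probe sets without expression, so its log2 values depend on the pseudocount (3.32 with that at the 40th percentile and 2.20 with 32). The cAMP-responsive regulator gene Crem read 135 and 119 against 25.0 and 24.9 (2.00, SE 0.39). The cyclooxygenase gene Ptgs2 read 3092 and 3693 at pH 6.4 in the TDAG8 line against 897 and 1510 in the control line (1.78, SE 0.28). Chac1, of the amino acid response, read 30.9 and 26.2 against 88.7 and 111 (-1.72, SE 0.35). None of these genes passed the limma test.

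**Figure D4:**
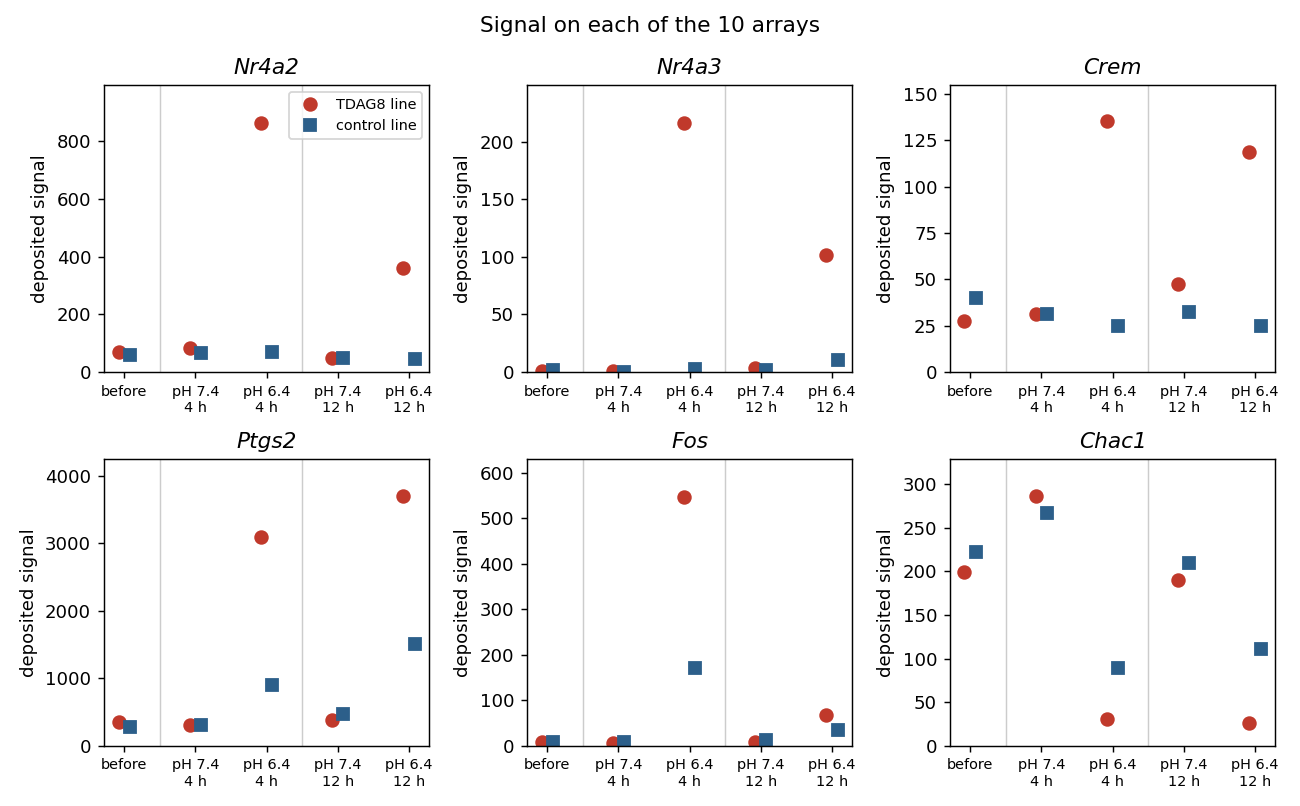
Deposited signal of 6 genes on each of the 10 arrays (linear scale from 0, circles TDAG8 line, squares control line), by condition. At pH 6.4 Nr4a2, Nr4a3, Crem, Ptgs2 and Fos read higher and Chac1 lower in the TDAG8 line than in the control line at both times, and Nr4a2 reaches 864 against 69.1 at 4 h.

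The other genes named by the rule, none of which passed, had a higher log2 pH difference in the TDAG8 line than in the control line for Apold1 (2.59), Crhbp (2.53), the protease inhibitor gene Slpi (2.39), the vitamin D receptor gene Vdr (2.34), Sel1l3 (2.25, with a signal of at most 15.1) and the interleukin gene Il6 (2.21, SE 1.35). The difference was lower in the TDAG8 line for Retn (-2.92), Engase (-2.68), Cys1 (-2.63), Batf2 (-2.26), Fgr (-2.0), Mmp23 (-1.97) and Rslcan18 (-1.96), all with signals of at most 29.9. These 7 genes, Crhbp, Vdr, Sel1l3 and Il6, and of the lists below Il11, Cxcl5, Gbp2, Ifit3 and Usp18, read under 6.6 on at least 1 array, so their values depend on the pseudocount. The list of cAMP and CREB targets had a larger pH response in the TDAG8 line by camera (adjusted p = 7.55e-10, and adjusted p = 0.884 with an estimated correlation). Of its 23 members 0 passed over all genes and 6 adjusted over the list alone. Its median difference was 1.09 at 4 h and 0.61 at 12 h, each at the 100th percentile of random lists. The amino acid and unfolded protein response list had lower pH differences in the TDAG8 line (adjusted p = 0.000119, and adjusted p = 0.884 with an estimated correlation). Its median difference was -0.054 at 4 h and -0.457 at 12 h, so it lay mainly at 12 h. Over all genes 0 of 20 passed either way, and Trib3 (-1.25), Slc7a5 (-1.12) and Ddit3 (-1.0) followed Chac1 in size. At 4 h and 12 h Trib3 was -0.69 and -1.8, Slc7a5 -0.21 and -2.04 (SE 0.73) and Ddit3 -0.67 and -1.33. The inflammatory list had higher pH differences in the TDAG8 line (adjusted p = 0.0127, and adjusted p = 0.884 with an estimated correlation), with medians of 0.437 at 4 h and 0.409 at 12 h. By gene, 0 of 17 passed and 1 adjusted over the list alone, with Il11 (2.15) and Cxcl5 (1.31) beside Il6 and Ptgs2. The interferon list had lower pH differences (adjusted p = 0.0348, and adjusted p = 0.884 with an estimated correlation). Its median difference was -0.055 at 4 h, at the 36.7th percentile of random lists, and -0.671 at 12 h, at the 0.04th. The list was lower in the TDAG8 line before treatment too, with a median line difference of -0.282. That difference was -0.273 and -0.388 at pH 6.4 (4 h and 12 h), and -0.081 and -0.023 at pH 7.4. From before treatment to pH 7.4 at 12 h the list rose by 0.577 in the TDAG8 line and 0.193 in the control line. The 12 h value thus rests in part on the pH 7.4 arrays. Taken singly, 0 of 13 passed either way, with values of -1.23 for Gbp2, -0.85 for Ifit2, -0.77 for Ifit3 and -0.75 for Usp18, and 0.05 for Usp18 without the control pair at 12 h. Epithelial markers had higher pH differences (adjusted p = 0.0348, and adjusted p = 0.894 with an estimated correlation), with medians of 0.171 at 4 h and 0.722 at 12 h. Among them, 0 of 4 passed and 1 adjusted over the list alone. The values were 1.71 for Krt18, 0.44 for Krt8, 0.40 for Epcam and -0.31 for Ocln. Epcam and Ocln had signals of at most 45.1 and 31.1. The other markers of the 10 fixed fell below the filter, so the list result rests mainly on Krt18 and Krt8. Epcam was -0.33 with the mean of its probe sets and -0.03 without the control pair at 12 h, and Ocln 0.25 without the TDAG8 pair at 12 h.

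By limma 0 of 12161 genes passed for the interaction, 339 had an unadjusted p under 0.05 where 608 are expected by chance, and the smallest adjusted p was 0.9999. The fit counts the change of the pH response from 4 h to 12 h as residual. That change correlated between the lines (Pearson's r 0.445 over all genes). In simulated data the fit recovered 2 and 96 of 100 genes changed by 1 and 3 with moderated variances. With drawn variances the fit recovered 0 and 0. The absence of passing genes thus does not show equal responses in the lines. The count was 0 under every alternative fixed in advance, pH by time in the model included. With settings chosen after seeing the data and pH by time in the model, which leaves 1 residual degree of freedom, 75 genes passed with trend and robust (50 with a higher and 25 with a lower pH difference in the TDAG8 line). Under the same model 105 passed with a pseudocount of 32 (68 and 37), 50 with that pseudocount and a signal of 50 or more (39 and 11), 8 with that signal filter, 1 with a filter at the 60th percentile and 0 with the values as deposited. The 75 included Nr4a2 (adjusted p = 1.84e-08), Ptgs2 (5.81e-08), Apold1 (1.92e-06), Slpi (1.17e-05) and Crem (0.00212) among the higher and Chac1 (4.07e-05), Ddit3 (0.00715) and Atf4 (0.0408) among the lower differences, and these last fell further in the TDAG8 line. Of the lists, 9 of 23 cAMP and CREB targets were higher and 4 of 20 amino acid and unfolded protein response genes were lower. The inflammatory list had 2 higher and 1 lower, the immediate early genes 1 and 1, the TGF-beta targets and the epithelial markers 1 higher each and the cell cycle genes 1 lower. These were Ptgs2, Cxcl1, Ccl2, Fos, Egr3, Id3, Krt18 and Ccnd1, named after their values were seen. Of them Ptgs2, Fos and Id3 are also cAMP and CREB targets and are counted among the 9 above. In simulated data with moderated variances, the test with pH by time, trend and robust made 52 false calls among 228 (22.8%). That share depends on the 200 changed genes planted there, so it does not carry over to the 75. The share of false calls among the 75 is unknown.

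Within the TDAG8 line alone, the pH response was 5.17 for Nr4a3 (SE 0.57, adjusted p = 0.117, a value that depends on the pseudocount as above), 4.05 for Ccn1, 3.73 for Ccl7, 3.32 for Ptgs2 (SE 0.20, adjusted p = 0.111), 3.30 for Crhbp, 3.28 for Arrdc4, 3.07 for Nr4a2 and 3.03 for Il11. It was -3.69 for Runx1t1, -3.37 for Cass4, -3.19 for Bnc1, -2.86 for Chac1, -2.78 for Nostrin, -2.75 for Jmjd4, -2.32 for Sh3yl1 and -2.19 for Zfp608. Both pairs gave the same sign for each of these genes, as the naming rule required, and none passed. On the side with the lower signal Crhbp, Il11, Cass4, Nostrin (2.0 and 1.8) and Jmjd4 (1.1 and 1.0) also read under 6.6 on at least 1 array. Within the control line the response was 3.55 for Arrdc4 (SE 0.24, adjusted p = 0.120), 3.46 for Ccn1, 3.11 for Cxcl2, 2.83 for Pik3ip1, 2.80 for Ankrd33b, 2.78 for Txnip, 2.74 for Ccl7 and 2.69 for Ccl2. It was -4.12 for Bnc1 (SE 0.26, adjusted p = 0.120), -3.15 for Runx1t1, -2.93 for Ppp1r10, -2.63 for Dcun1d4, -2.41 for Hexim1, -2.26 for Ackr3, -2.23 for Osr2 and -2.21 for Gata4, and none passed. There Pik3ip1 (1.4 and 3.0), Dcun1d4 (1.6 and 1.8), Gata4 (1.7 and 1.8) and Ppp1r10 read under 6.6 on at least 1 array, and for all genes named so the log2 values depend on the pseudocount.

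By camera 9 lists passed in the TDAG8 line and 4 in the control line, and 0 passed with an estimated correlation in either. The inflammatory list was higher at pH 6.4 in the TDAG8 line (adjusted p = 1.06e-12, and adjusted p = 0.383 with an estimated correlation, 13 of 17 rising adjusted over the list alone). It was so in the control line (adjusted p = 3.17e-08, and adjusted p = 0.586 with an estimated correlation, 10 of 17). The immediate early genes were higher in the TDAG8 line (adjusted p = 0.000118, and adjusted p = 0.603 with an estimated correlation, 8 of 15). They were so in the control line (adjusted p = 2.96e-07, and adjusted p = 0.721 with an estimated correlation, 7 of 15), with Fos at 4.34 and 2.83. SRF targets were higher in the TDAG8 line (adjusted p = 0.000414, and adjusted p = 0.603 with an estimated correlation, 1 of 14) and in the control line (adjusted p = 0.00247, and adjusted p = 0.807 with an estimated correlation, 2 of 14). Cholesterol synthesis genes were lower in the TDAG8 line (adjusted p = 0.0012, and adjusted p = 0.783 with an estimated correlation). They were lower in the control line too (adjusted p = 0.00181, and adjusted p = 0.807 with an estimated correlation), with 0 of 16 adjusted over the list alone and Mvk at -1.33 and -1.10.

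In the TDAG8 line cAMP and CREB targets were higher (adjusted p = 0.00044, and adjusted p = 0.603 with an estimated correlation, 9 of 23 rising adjusted over the list alone). The median pH response of that list was 1.06 at 4 h (100th percentile of random lists) and 0.245 at 12 h (95.4th), so it lay mainly at 4 h. The amino acid and unfolded protein response list was lower (adjusted p = 0.00044, and adjusted p = 0.655 with an estimated correlation, 6 of 20 falling adjusted over the list alone). In the control line these lists had adjusted p = 0.788 and 0.140. The interaction lists above test that difference. In the TDAG8 line the oxidative stress list (adjusted p = 0.0281, and adjusted p = 0.662 with an estimated correlation, 1 of 10) and TGF-beta targets (adjusted p = 0.0287, and adjusted p = 0.655 with an estimated correlation, 3 of 10) were higher. Fibroblast markers were lower (adjusted p = 0.0281, and adjusted p = 0.603 with an estimated correlation, 1 of 6). Members had values of 1.15 for Osgin1, 1.94 for Id3 and -1.80 for Pdgfra. For the last 3 lists the control line gave adjusted p = 0.297, 0.140 and 0.0963, and the difference between the lines did not pass (adjusted p = 0.172, 0.520 and 0.768). By limma 0 genes passed in each line, with 1901 genes at an unadjusted p under 0.05 in the TDAG8 line and 1922 in the control line. The fit is that of the interaction, with the change from 4 h to 12 h counted as residual. Other settings gave 31 and 10 genes with arrays centred on the median, 13 and 3 with a filter at the 60th percentile, 1 and 5 with the mean of all probe sets, 74 and 27 with trend and robust, and 24 and 0 with a pseudocount at the 40th percentile.

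The comparison of 12 h with 4 h asked what changed with time under treatment in both lines. Kif26a, a kinesin family gene, was higher at 12 h by 1.95 (SE 0.16, adjusted p = 0.337, higher in 4 of 4 pairs). It was followed by the chemokine gene Ccl5 (1.61), Nphp4 (1.52), Tnk1 (1.22), the DNA demethylation gene Tet2 (1.22), Osr2 (0.86), the lysosomal membrane gene Scarb2 (0.82) and Cxcl17 (0.79). Crybb3 (-1.53), Diras1 (-1.29), Fbxw19 (-1.27), Ubqlnl (-1.05), Paqr5 (-0.88), Nr4a2 (-0.78), Tcf19 (-0.62) and the DNA polymerase gene Pole (-0.62) were lower in 4 of 4 pairs, as the naming rule required. None of these genes passed, and Nphp4, Tnk1, Cxcl17, Crybb3, Diras1, Fbxw19, Ubqlnl and Paqr5 had signals of at most 22.3, near the lower end of the array. These, Kif26a and Ccl5 read under 6.6 on at least 1 array, so their values depend on the pseudocount. As lists, the cell cycle genes were lower at 12 h (adjusted p = 0.000173, and adjusted p = 0.883 with an estimated correlation), with values of -0.47 for E2f1, -0.46 for Ccnb2, -0.44 for Mcm2 and -0.39 for Bub1b. Cholesterol synthesis genes were lower too (adjusted p = 0.000632, and adjusted p = 0.883 with an estimated correlation), with values of -0.81 for Mvk, -0.61 for Dhcr7, -0.59 for Mvd and -0.50 for Stard4. These 4 came mainly from the pH 6.4 pairs, as for Mvk with -1.62 and -1.20 at pH 6.4 and -0.32 and -0.12 at pH 7.4 (TDAG8 and control lines). Of either list 0 members passed, over all genes or adjusted over the list alone. By limma 0 of 12161 genes passed, 1420 had an unadjusted p under 0.05, the smallest adjusted p was 0.337, and the count was 0 under all other settings. A change with time that differed between pH 6.4 and pH 7.4 was counted as residual in this fit.

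Differences between single arrays, which carry no test, showed the size of each response. At pH 6.4 against pH 7.4, 410 genes were higher and 693 lower by 2-fold or more in the TDAG8 line at 4 h, and 706 and 952 at 12 h. In the control line the numbers were 397 and 734 at 4 h and 724 and 1057 at 12 h. The pH response of the TDAG8 line was above that of the control line by 2-fold or more for 441 genes at 4 h and 497 at 12 h, and below it for 432 and 454. Of these, 80 were above at both times where independence would give 18.0, 60 were below at both (16.1) and 116 went opposite ways (34.1). Among genes with a signal of 50 or more the numbers were 23 (1.15), 11 (0.685) and 10 (1.79). All of them exceed independence, the opposite ones included. Across genes, the difference in pH response between the lines at 4 h correlated only weakly with that at 12 h. Pearson's r was 0.082 over 12161 genes and 0.221 over the 8957 with a signal of 50 or more. Compared with cells before treatment, pH 7.4 medium gave 111 higher and 151 lower genes in the TDAG8 line at 4 h and 158 and 143 at 12 h, and 191 and 194, and 259 and 191, in the control line. In these comparisons the median of the cholesterol synthesis genes was 0.19 and 0.20 in the TDAG8 line (4 h and 12 h) and 0.21 and 0.33 in the control line. The cell cycle medians were -0.10 and -0.44, and -0.08 and -0.33, and the inflammatory medians -0.38 and -0.06, and -0.44 and -0.48.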

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

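The gene list tests of the interaction were fixed before the data were examined. Of the tests of explanations in this part, those on unnamed probe sets and on the line difference before treatment were fixed before their results were seen, and the others were chosen only after the result was seen.

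The pH response of the cAMP and CREB targets was larger in the TDAG8 line than in the control line, by a median of 0.50 on the log2 scale over 23 genes (camera adjusted p = 7.55e-10, lost at adjusted p = 0.884 with an estimated correlation and 0.438 by fry). A single deviating array would raise the list at 1 time, whereas the lower of its percentiles among random lists at 4 h and 12 h was 100. Scaling between arrays would lose the difference under another scaling, and the lowest median over both times and both other scalings was 0.56. All scalings start from the deposited values, whose log2 medians spanned 0.2, so they could move the list only a little. Scaling as a cause is thus not excluded. A standing difference between the lines cancels in this comparison, and the median line difference of the list was 0.13 before treatment and 0.04 and 0.12 at pH 7.4 (4 h and 12 h), against 1.07 and 0.65 at pH 6.4. Signalling of the receptor under acid is a candidate explanation that stays open as a hypothesis, found and tested on the same 8 arrays, and neither a clonal difference in acid response between the lines nor the level of the receptor was tested.

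The B1 repeat probe set, which no comparison used, read at least 1.79 times higher on the pH 6.4 arrays at 12 h than on any other array. Its fold from pH 7.4 to pH 6.4 at 12 h was 2.17 in the TDAG8 line and 4.07 in the control line, and at 4 h 0.99 and 1.73. Stronger hybridisation or scaling of those arrays would raise the spiked bacteriophage RNA as much, and its larger fold was 1.19, and RNA degradation would raise the 3' to 5' ratio of Gapdh, whose larger fold was 0.96. More RNA from outside annotated genes would raise probe sets without a gene symbol against named ones of like level in both lines, and the smaller shift was -0.13. Another RNA make-up of those samples would raise small ribosomal RNA (18S) in both lines, and its fold at 12 h was 0.57 in the TDAG8 line and 6.82 in the control line, and at 4 h 0.98 and 1.66. The 18S signal ranged from 526.6 to 4255 over the arrays, and the control array at pH 7.4 and 12 h had the lowest. With 1 array per line and condition and the lines going opposite ways, another RNA make-up and an effect of acid on B1 transcripts cannot be told apart. Both stay open. The other explanations were tested only through 1 spiked RNA, the Gapdh ratio and unnamed probe sets, so forms that spare these are not excluded. Which transcripts carry the repeat was not tested.

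The line difference at pH 6.4 could reflect signalling of the receptor under acid or a difference that stands without acid. Among 100 genes that differed by 1 or more in both pH 6.4 pairs, 78 of them higher in the TDAG8 line, the median difference before treatment was 16% of that at pH 6.4, below the limit of 20% set for signalling, and 69 had the same direction. The medians were 0.25 before treatment and 0.31 and 0.39 at pH 7.4 (4 h and 12 h), against 1.56 at pH 6.4. That reading was tightened after the value was seen, since genes chosen for their size at pH 6.4 and near the floor of the array regress towards 0, and brighter genes were required to give the same answer. Among the 48 such genes with a signal of 50 or more, where independence would give 1.90 and 45 were higher, the share was 24.0%, 42 had the same direction before treatment, and 14 kept at least 50% of the difference there. Their medians were 0.42 before treatment and 0.32 and 0.54 at pH 7.4, against 1.76 at pH 6.4. The explanations cannot be told apart for these genes, because their choice at pH 6.4 lowers the share and each value before treatment rests on 1 array per line.

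The median interaction of the amino acid and unfolded protein response list was -0.25, and its call by camera was lost (adjusted p = 0.884) with an estimated correlation. By time the median was -0.054 at 4 h and -0.457 at 12 h. The median interactions of the inflammatory list, the epithelial markers and the interferon list were 0.41, 0.42 and -0.52, and their calls by camera were lost too (adjusted p = 0.884, 0.894 and 0.884 with an estimated correlation). At 4 h and 12 h the medians were 0.437 and 0.409, 0.171 and 0.722, and -0.055 and -0.671, in the same order. By fry 0 lists passed for the interaction. For 8 of 114 named genes, both pH differences had one sign in the TDAG8 line and the other sign in the control line, a difference that was not tested by that sign rule and that did not pass as an interaction by limma: Apold1 (2.59), Sel1l3 (2.25), Crem (2.00), Cxcl5 (1.31), Krt8 (0.44), Rslcan18 (-1.96), Batf2 (-2.26) and Cys1 (-2.63). Over all 12161 genes 507 showed such signs, 4.17% where 12.5% are expected for independent signs.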

How the results depend on the processing

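Of the settings in this part, the values as deposited, the pseudocount of 32, the filter for a signal of 50 or more and every combination with pH by time were chosen only after the result was seen. The line and pH counts moved with the filter, the variance model and the pairs used, and the interaction count was 0 under every setting fixed in advance. Of the named gene values under other settings, 0 of 692 reversed for the line comparison, 1 of 1520 for pH in both lines, 4 of 581 for the interaction, 2 of 626 and 0 of 411 within the TDAG8 and control lines, and 0 of 353 for time. Besides list members, the naming rule took genes that passed or had the same sign in every pair. Taken alone, other filters, trend and robust, no block and pH by time change which genes pass but leave the fitted log2 value as it was. The same holds within a line when a pair of the other line is left out. No value could reverse there. Few reversals thus follow largely from the naming rule and from these settings, and are no separate sign of stability. With the direction kept, 84 and 224 values no longer passed for the line comparison and pH in both lines. Those that newly passed were 54 and 169, 49 for the interaction, 91 and 36 within the TDAG8 and control lines, and 0 for time. Scaling to a common trimmed mean and quantile normalisation remove a change of all transcripts alike, which therefore cannot be seen, and the deposited values include signals near background at which small differences cannot be resolved. Where a count moved, the cause was not tested.

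With arrays centred on the median, 89 genes passed between the lines, 31 for pH in the TDAG8 line and 10 in the control line. The share of passing genes that were higher moved from 56.2% to 65.2% between the lines (67.9% with the values as deposited), and from 44.6% to 32.4% for pH in both lines (33.1% with the values as deposited, and 37.4% with pH by time as well). The latter share was 52.0% with the mean of all probe sets, and the former ranged from 50.2% to 88.9% over the settings that changed neither block nor arrays. With no filter, 9 genes passed between the lines and 241 for pH in both lines. With a filter at the 60th percentile the counts were 588 and 1919, and 13 and 3 for pH in the TDAG8 and control lines. With the mean of all probe sets, 1 and 5 genes passed for pH in the TDAG8 and control lines. There Slc7a11 was -0.40 for pH in both lines and -0.33 in the TDAG8 line, and the Epcam interaction was -0.33. With trend and robust, 881 genes passed between the lines, 2076 for pH in both lines, and 74 and 27 within the TDAG8 and control lines. With the pseudocount at the 5th percentile 96 passed between the lines, and with that at the 40th percentile 264, and 24 for pH in the TDAG8 line. With no block 15 passed between the lines and 1863 for pH in both lines, with the treated arrays only 6 passed between the lines, and with pH by time added 3397 passed for pH in both lines.

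With each pair left out in turn, the count between the lines ranged from 4 to 28 and that for pH in both lines from 0 to 278. The Ocln interaction ranged from -0.87 to 0.25, that of Usp18 from -1.54 to 0.05 and that of Epcam from -0.029 to 0.82. The pH response of Actg2 in the TDAG8 line ranged from -0.055 to 2.19.

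Of the settings chosen after seeing the data, the pseudocount of 32 gave 757 genes between the lines, 2244 for pH in both lines, and 92 and 33 within the TDAG8 and control lines. A signal of 50 or more gave 645, 1897 and, in the TDAG8 line, 19. Both together gave 859, 2110, 56 and 3. With pH by time added, pH in both lines had 4302 genes with the filter at the 60th percentile, 3384 with the values as deposited, 4703 with the pseudocount of 32, 4253 with a signal of 50 or more and 4499 with both. The interaction then had 1 gene with the filter at the 60th percentile, 105 with the pseudocount of 32, 8 with a signal of 50 or more, 50 with both and 75 with trend and robust. In simulated data the last of these gave 22.8% false calls, a share that depends on the planted genes and does not carry over to the 75.

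With an estimated correlation 0 gene lists passed in each of the 6 comparisons. That test also uses the few residual degrees of freedom, so the loss cannot be put down to correlation among the genes alone. For the glycolysis and hypoxia list between the lines the estimated correlation was -0.005, below the preset 0.01. Its camera p still went from 1.28e-06 to 0.00634. With fry 0 lists passed for the interaction, for pH in the TDAG8 line, for pH in the control line and for time, and 4 and 9 for the line comparison and pH in both lines.

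For differences between single arrays, a limit of 0.58 gave 2926 and 4184 genes for pH in the TDAG8 line (4 h and 12 h), 2995 and 4268 in the control line, and 2081 and 2537 for the response of the TDAG8 line against the control line. For pH 7.4 against before it gave 886 and 1245 in the TDAG8 line and 1093 and 1616 in the control line. No filter gave, in the same order, 2360 and 2944, 2541 and 3287, 3041 and 3142, 1442 and 1465, and 1797 and 1895. The pseudocount at the 40th percentile gave 432 and 484 for the response of the TDAG8 line against the control line, and 73 and 103, and 105 and 167, for pH 7.4 against before.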

Other observations

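The comparisons and tests in this part, the splits of the arrays included, were all chosen only after the result was seen.

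The pH responses at 4 h and 12 h were set against each other, with the lines as repeats. The median pH response of the cholesterol synthesis genes was -0.12 at 4 h and -0.94 at 12 h in the TDAG8 line, and -0.21 and -0.97 in the control line. The change from 4 h to 12 h passed for 0 of 16 members over all genes and for 12 adjusted over the list alone (camera adjusted p = 5.76e-08, and adjusted p = 0.609 with an estimated correlation). The 3 measured replication-dependent histone genes went from medians of 1.12 and 1.92 at 4 h to -0.57 in both lines at 12 h (camera adjusted p = 0.00284, and adjusted p = 0.642 with an estimated correlation, 3 of 3 adjusted over the list alone). The glycolysis and hypoxia list (camera adjusted p = 0.023, median -0.305, 3 of 18 adjusted over the list alone), the matrix and protease list (0.023, -0.281, 5 of 14) and the lysosome and autophagy list (0.0283, -0.295, 1 of 18) also had lower pH differences at 12 h. Each had adjusted p = 0.642 with an estimated correlation. Lists that did not pass had members changing both ways adjusted over the list alone (camera adjusted p of 0.154 or more for each). Lower at 12 h were 3 of 6 fibroblast markers, 3 of 15 immediate early genes, 3 of 13 p53 targets, 1 of 16 apoptosis genes and 1 of 15 genes of the protein kinase A pathway. Higher were 2 apoptosis genes and 1 each of the immediate early genes, p53 targets, oxidative stress genes, leukocyte markers and endothelial markers. Over 12161 genes 0 passed by limma, with 3135 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0993. Among 8957 genes with a signal of 50 or more, 1483 passed, 823 with a higher and 660 with a lower value at 12 h. They included 11 of 16 cholesterol synthesis genes, all lower, 3 of 24 cell cycle genes, all higher, and 4 of 14 apoptosis genes, 3 of them higher. The cell cycle share was no larger than that over all genes, 1483 of 8957. Also lower were 3 of 4 fibroblast markers and 3 of 11 matrix and protease genes. Of 12 p53 targets 3 were lower and 1 higher. In that set Fosl1, an AP-1 subunit gene, went from -0.17 and -0.27 at 4 h to 2.05 and 1.78 at 12 h in the TDAG8 and control lines (2.13, adjusted p = 0.0229), and the clock gene Per2 from 0.05 and 0.12 to 1.80 and 2.23. Il15ra (2.95), Arhgap39 (2.93) and Rbbp6 (2.31) had higher values at 12 h. H2aw, a histone gene, went from 2.11 and 2.51 to -0.50 and -0.53 (-2.83, adjusted p = 0.0188). Sned1 (-2.92), H1f2 (-2.46), the noncoding RNA Neat1 (-2.40), Tenm4 (-2.33), Acp2 (-2.32), the growth factor gene Vegfd (-2.19) and Mmab (-2.15) had lower values.

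For a hypothesis that the pH response changes with time alike in both lines, the change was correlated between the lines across genes, which are not independent replicates. Pearson's r was 0.445 and Spearman's coefficient 0.509 over 12161 genes, and Pearson's r was 0.714 for genes with a signal of 50 or more. These lie above a limit of 0.3 that was set after the result was seen. The correlations of the pH responses at the same time and across times, given in the Results, largely fix these values, so they are no separate test. The values are consistent with a change that the lines share. The 2 arrays at pH 6.4 and 12 h, on which it rests in part, also stood apart from the other 8 in their B1 repeat signal (2602 and 3587 against 844 to 1456), which is left open above. A technical property common to these 2 arrays was thus not separated from a time course of the acid response, which stays a hypothesis found on these arrays and not tested on others.

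The fits used matched pairs, so the real split was compared with every other split that parts all the pairs. For the line comparison 1 of 16 such splits, the real one, gave as many genes, with 146 genes against a highest other count of 0. For pH in both lines 1 of 8 gave as many, with 1220 genes against 0. These splits are too few for a share under 5%. For 12 h against 4 h the real count was 0, so that 8 of 8 splits gave as many whatever the data, and the comparison says nothing. Splits that leave some pairs together leave the compared effect in the residual, and those that part no pair were fitted without the block, so they were not used for this. A split setting 12 h against 4 h only at pH 6.4 called 2324 genes, and the like split at pH 7.4 called 0. The first points to a structure of the samples. Each leaves the time effect at the other pH in the residual, so the counts do not compare the 2 pH values, and the test of the difference itself is given above.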
